A study of Mus musculus with 2 samples.

How the data were processed

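H3K36me3 ChIP-seq was carried out on hearts from pooled mouse embryos at 14.5 days, per the labels, with library fragments of 300 to 500 bp. The labels name 2 biological replicates, of which replicate 1 joins 2 technical replicates and replicate 2 has 1. Both carry the same label for the donor strain, and each is a pool of embryos of both sexes.

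The authors deposited peak lists in narrowPeak form on mm10, per the labels: 1 for each replicate, 1 called on the pooled replicates and 1 named replicated peaks. Per the text deposited with the lists, the list of replicate 1 was made from its joined alignments and 2 further files, that of replicate 2 from its alignments and 1 further file, and the replicated list from both replicate lists and the pooled list. What the further files hold, the aligner, the peak caller, its version and its threshold are not given in the sources used here. Each peak has a score and a signal value, both as the authors deposited them; the score is capped within each list, and the unit of the signal is not stated. The deposited lists also give −log10 of a p-value and of a q-value for each peak. Score and signal are the authors' own values for a peak, and signal was used only to describe or rank peaks within a list, and in 1 closing test to pair peaks of like signal. Read counts are not part of the lists, so depth is unknown and no interval that needs counts is given.

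The rule behind the replicated list was tested on the files. All 111540 of its peaks were peaks of the pooled list. A rule of at least 50% overlap, of either peak, with a peak of each replicate was met by 89239 pooled peaks, all of them in the replicated list, which held 22301 more.

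Annotation was GENCODE release 21 for mouse with the GRCm38 sequence, the same build as the lists: no peak passed the end of a chromosome. Chromosomes 1 to 19, X and Y were used, with gaps of at least 1 kb left out of the 2648 Mb of assembled bases. Peaks of a list were merged before bases were counted. The gene body was the annotated gene from first to last base, and the covered share was the part of it inside merged peaks. A protein-coding gene of at least 1 kb was called marked at a covered share of at least 20% in the replicated list. Members of gene lists and families were counted by the same share at any length. Background windows were placed once for each gene at the same length, at least 5 kb from any annotated gene, with seed 1, and 21195 fitted; the limit for a count of 0 is 3 windows of the total. The profile used 20 equal bins from TSS to TES. Coding exon and intron coverage used genes with at least 3 merged exons. The list tests set the median covered share of a list against 10000 random lists of the same size matched on deciles of gene length, as a description of these libraries. The marked members of random lists were counted as well, an addition made after the data were examined.

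There is 1 group, so replicates were compared by shared bases, shared peaks and covered shares of genes, and values are given per replicate or as mean and SD of 2. The threshold of 20%, 15 gene lists with 253 genes, 10 families set by patterns of symbols, the alternatives and the rule for named genes were fixed before the data were examined. The lists held markers of cardiac muscle, cardiac transcription factors, conduction and calcium handling, endothelium, fibroblasts with epicardium and matrix, smooth muscle with pericytes, erythroid and myeloid cells, housekeeping genes, enzymes and readers of the mark, cell cycle, neurons, liver, lung with foregut, and skeletal muscle progenitors. The rule named the most and least covered members of each list, any member of the cardiac muscle and transcription factor lists, the 10 genes of at least 10 kb with the largest covered share, the 5 with the largest difference between the replicates in each direction, the 10 peaks with the highest signal, the 5 genes with the most covered bases and the 5 longest intergenic regions. Pgk1, Hprt, Setd2, Eif4a1, Xirp1, Csf1r, Pln and a few other list members or neighbours were named after their values were seen.

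The alternatives were peaks with a q-value of at most 0.01, each replicate's own list, the pooled list, other overlaps for a shared peak, thresholds of 10% and 40%, longer genes, genes that overlap no other gene, other backgrounds, all annotated genes, exons and introns without the first, and all chromosome bases as the denominator. Peaks of the replicated list with at least 50% of their length in peaks of each replicate were added as an alternative after the data were examined.

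The code was tested on simulated data. Interval arithmetic gave the same bases as a base-by-base count in all 200 simulated pairs of sets. Of 200 protein-coding genes given peaks of known covered share, all 164 at or over the threshold were recovered, no other of the 21221 genes was marked, and the largest error of a covered share was 0.004 percentage points. Among 200 random lists with no signal, 5.5% fell outside the middle 95% of their random lists. In the matched comparison of the X, 4000 simulated X peaks with no effect of their own differed from matched autosomal peaks by -1.13 percentage points. That simulation set the chance of being found by −log10 p alone, so it cannot test this assumption. Computation used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.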

Results

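Trimethylation of histone H3 at lysine 36 (H3K36me3), a mark laid down along the body of transcribed genes, was profiled by ChIP-seq in hearts of pooled male and female mouse embryos at 14.5 days of development. The series held 1 group of 2 biological replicates, and no other tissue or stage, so the comparisons are between the replicates and between places and genes within each library. No test between groups exists, and no p-value is given. Each library is described by its own peak list, and the authors also deposited a pooled list and a list they call replicated. The peak lists carry no read counts, so the sequencing depth behind each value is unknown. Coordinates are on mm10, 1-based.

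Replicate 1 held 172424 peaks over 135 Mb, 5.11% of the assembled main chromosomes, and replicate 2 held 176353 peaks over 106 Mb, 3.99%. The peaks of replicate 1 were wider, with a median of 415 bp against 364 bp, and 301 of them reached 10 kb or more against 67 in replicate 2. The replicated list held 111540 peaks over 140 Mb, 5.28% of the assembled bases, with a median width of 708 bp and a longest peak of 53117 bp. Every peak of the replicated list was also in the pooled list of 170412 peaks. Of its peaks, 80.0% overlapped a peak in each replicate by at least 50% of either peak, and 21465 had no overlapping base in at least 1 of the replicates, so the name does not mean that each peak was called in both.

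Of the 10 peaks with the highest signal in the replicated list, 4 lay in zinc finger genes. The leading peak lay in Zfp26 on chromosome 9 (20435184 to 20442978), with a signal of 17.5, and 34.0% of its bases were coding exon, 26.6% UTR and 39.4% intron. The next 2 both lay in Zfp68 on chromosome 5 (138604632 to 138608857 and 138610287 to 138618587), and Zfp329 on chromosome 7 (12807367 to 12811731) ranked 6. Tpm1, which encodes the thin filament protein tropomyosin, held the peak of rank 5 on chromosome 9 (67026850 to 67036576), 64.2% of it intronic. The others lay in Srrm2 and Elob (1 peak across both), Nedd4, Serinc1, Actb and Rbm39, with signals from 14.9 to 16.0. Each of the 10 peaks was covered by peaks of replicate 1 over at least 88.4% of its length and of replicate 2 over at least 76.5%.

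The replicates shared most of their marked bases and nearly the same ranking of genes. Sf3a1, a splicing factor gene, was covered over 94.8% of its body in replicate 1 and 92.6% in replicate 2, and Trrap, which encodes a subunit of histone acetyltransferase complexes, over 92.9% and 91.2%. Ttn, the gene of the giant sarcomere protein titin, was covered over 91.6% and 86.5%. Across 21221 protein-coding genes of at least 1 kb, the covered shares of the gene body had a Pearson r of 0.980 and a Spearman rho of 0.975, which describe agreement across genes, not across independent samples. The mean absolute difference was 3.80 percentage points over all these genes, and 7.01 (Pearson r 0.967) over the 11500 covered in either replicate.

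**Figure D1:**
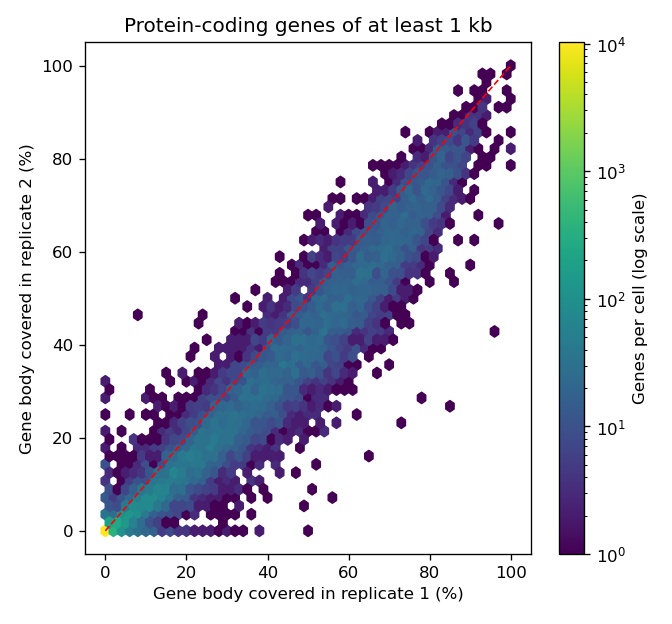
Share of the gene body covered by H3K36me3 peaks in replicate 1 (x axis, %) and replicate 2 (y axis, %) for 21221 protein-coding genes of at least 1 kb; colour gives the number of genes per cell on a log scale and the dashed line marks equal shares. Most covered genes lie below the line: 10155 genes had the larger share in replicate 1 and 1343 in replicate 2.

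By bases, 66.2% of the peak bases of replicate 1 lay in peaks of replicate 2, and 84.7% of those of replicate 2 lay in peaks of replicate 1, with a Jaccard index of 0.591. Independent lists of the same size would share 3.99% and 5.11%; the 89.5 Mb shared were 16.6 times that. Within gene bodies alone, the shares were 66.7% and 85.0% against 9.72% and 12.4% for independent lists, or 6.86 times. Counted as peaks with at least 50% of their own length in the other list, 51.3% of replicate 1 peaks and 77.4% of replicate 2 peaks were found. That share rose with the strength of the peak: from 25.3% in the weakest quartile of replicate 1 peaks by −log10 p to 88.7% in the strongest, and from 56.8% to 97.9% in replicate 2. With a reciprocal overlap of 50%, the shares fell to 33.5% and 32.8%.

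Genes with a larger share in replicate 1 outnumbered the reverse. Dffb, which encodes the DNase of apoptotic DNA fragmentation, was covered over 54.8% in replicate 1 and 21.9% in replicate 2. Rexo2, an RNA exonuclease gene, was covered over 53.7% and 20.9%, Zfp51 over 53.4% and 23.3%, the condensin gene Ncapg over 47.3% and 17.7%, and 2310057M21Rik over 75.0% and 45.4%. In the other direction, Ltbp3, which encodes a binding protein of latent TGF-beta, had 10.8% in replicate 1 and 28.9% in replicate 2. Midn had 66.6% and 79.4%, Ajuba 41.6% and 54.0%, the collagen gene Col1a1 22.2% and 34.5%, and Nos3, the endothelial nitric oxide synthase gene, 12.8% and 24.6%. At the 20% threshold used to call a gene marked, 1036 genes were marked in replicate 1 only and 66 in replicate 2 only, with 6409 marked in both against 2272 for independent lists. With 1 library on each side, none of these differences between replicates could be tested.

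The mark lay almost wholly in genes. Gene bodies of protein-coding genes, 39.3% of the assembled bases, held 95.5% ± 0.218 (SD, n = 2) of peak bases, a ratio of 2.43 ± 0.00555 (SD, n = 2). Coding exons had the largest ratio, 7.89 ± 0.683, followed by UTRs and noncoding exon parts at 5.85 ± 0.0871, the 1 kb either side of an annotated TSS at 3.88 ± 0.206 and introns at 2.00 ± 0.0256 (SD, n = 2 each). The TSS class takes in every annotated transcript start of protein-coding genes, including starts inside gene bodies, and no starts of other genes. Introns still held 71.5% ± 0.914 (SD, n = 2) of peak bases, since they make up 35.7% of the assembled bases. Intergenic bases, 54.0% of the assembly, held 3.77% ± 0.159 (SD, n = 2) of peak bases, a ratio of 0.0699.

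Only 236 of 111534 merged regions of the replicated list lay at least 5 kb from any annotated gene, and they made up 0.0963% of its bases. The longest, of 3112 bp, was on chromosome Y (90737461 to 90740572), 12.5 kb from the pseudogene Mid1-ps1. The next were on chromosome 2 (84590766 to 84593469), 6.60 kb from Ctnnd1, on chromosome 7 (28193675 to 28195414), 6.38 kb from Dyrk1b, on chromosome 6 (83998061 to 83999763), 8.51 kb from Zfp638, and on chromosome 3 (27088514 to 27089839), 7.38 kb from Ect2. The region near Ctnnd1 was covered over 94.8% by replicate 1 peaks and over 27.6% by replicate 2 peaks.

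Along the gene, coverage was lowest at the start and rose toward the 3′ end. In 5658 marked genes of at least 10 kb, divided into 20 equal bins from TSS to transcription end site (TES), bin 1 was covered over 2.58% ± 0.517 and bin 19 over 65.3% ± 7.34 (SD, n = 2), with bin 20 at 58.9% ± 7.74. The ratio of bins 11 to 20 over bins 1 to 10 was 1.81 in replicate 1 and 1.88 in replicate 2. The ratio of bin 20 to bin 1 was 23.0 ± 1.61 (SD, n = 2). In the replicated list, 4970 of the 5658 genes (87.8%) had more coverage in bins 11 to 20, and 688 had more in bins 1 to 10. Genes were chosen as marked by the replicated list, which draws on both libraries.

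**Figure D2:**
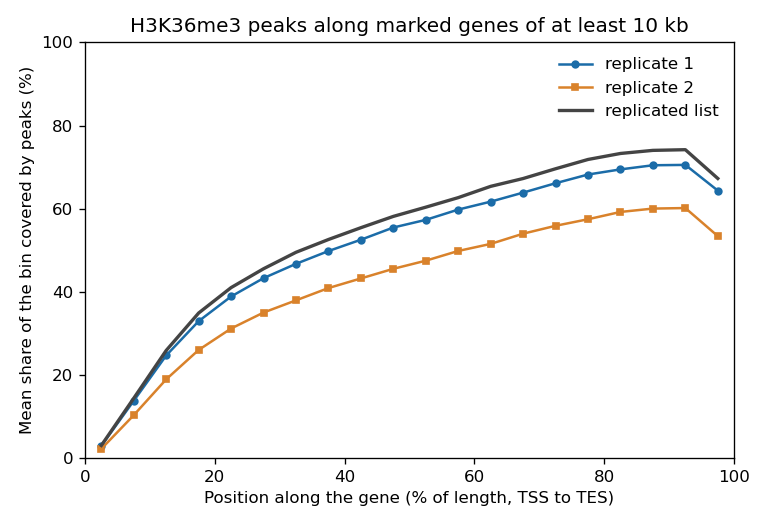
Mean share of each of 20 bins covered by H3K36me3 peaks (y axis, %) against position from TSS to TES (x axis, % of gene length) in 5658 marked protein-coding genes of at least 10 kb; points are the values of each replicate and the grey line the replicated list. Coverage rises from 2.94% and 2.21% in the first bin of replicates 1 and 2 to 70.5% and 60.1% in bin 19.

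Pooled over these genes, coding exon bases were covered more than intron bases. In 5623 marked genes of at least 10 kb with at least 3 exons, coding exon bases were covered over 77.4% ± 5.22 and intron bases over 37.2% ± 5.96 (SD, n = 2). The ratio was 1.96 in replicate 1 and 2.24 in replicate 2. Bases of all genes were summed before the shares were taken, so genes with long introns weigh more in the intron share. Exons and introns were not compared within single genes. First exons and introns lie in the sparsely covered start of the gene; without them the ratio in the replicated list was 1.71 against 1.92 with them.

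A gene was called marked when peaks of the replicated list covered at least 20% of its body. By this rule 7561 of 21221 protein-coding genes of at least 1 kb (35.6%) were marked, and 6960 ± 686 (SD, n = 2) by the replicates' own lists. Of the 7561, 6408 also passed the threshold of 20% in both replicates' own lists. Of the 21221 genes, 10425 (49.1%) had no base in a replicated peak and 4170 were covered over at least 50%. None of 21195 windows of the same lengths, placed at least 5 kb from any gene, passed the rule in any of the 4 lists, which allows a share of up to 0.0142%. The marked share varied with gene length, from 21.6% of genes of 1 to 5 kb to 46.2% of genes of 10 to 50 kb and 16.2% of genes of at least 100 kb. Peaks carry no strand, so overlapping genes share them; among 11180 genes that overlap no other annotated gene, 3298 (29.5%) were marked.

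The 10 genes of at least 10 kb with the largest covered shares held 3 splicing factor genes and 2 genes of heart muscle function. After 1700109H08Rik (99.7% in the replicated list) came Atp2a2, which encodes the calcium pump of the sarcoplasmic reticulum, on chromosome 5 (122453513 to 122502225), with 96.1% in the replicated list and 91.1% ± 3.94 (SD, n = 2) in the replicates. Trrap had 95.8%, the ubiquitin ligase gene Rnf40 95.7%, and Sf3a1 95.5%. Igf2r, the imprinted gene of the IGF2 receptor, had 95.3%, the splicing genes Snrnp200 and Sf3b3 95.2% and 94.7%, and the importin gene Kpnb1 94.8%. Mybpc3, which encodes cardiac myosin-binding protein C, on chromosome 2 (91118144 to 91136516), had 94.9% in the replicated list and 90.9% ± 4.98 (SD, n = 2) in the replicates. Among these 10 genes, only Sf3a1, Snrnp200 and Mybpc3 overlap no other annotated gene, so peaks over the others, 1700109H08Rik included, may be shared.

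By the number of covered bases, Gm20388 and Fgfr2 led with 621 kb and 276 kb, but the annotation gives them loci of 4435 kb and 2961 kb that span many other genes, and their covered shares were 14.0% and 9.33%. Ttn followed with 258 kb of its 279 kb locus on chromosome 2 (76703980 to 76982547), then Ryr2, the gene of the cardiac calcium release channel, with 206 kb of 554 kb, and the L-type calcium channel gene Cacna1c with 168 kb of 609 kb.

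Genes of the contractile apparatus were covered far more than random genes of the same lengths. Of 23 cardiac muscle genes, 18 were marked, the same number in each replicate's own list, and their median covered share of 71.6% lay above all of 10000 random lists matched on gene length (percentile 100, random median 0.948%). After Mybpc3 and Ttn came Tnnt2, cardiac troponin T, with 90.7% in the replicated list and 84.6% ± 2.36 (SD, n = 2) in the replicates, and Tpm1 with 86.4%. The neighbouring myosin heavy chain genes Myh6 (86.3%) and Myh7 (84.0%) on chromosome 14, and the cardiac actin gene Actc1 (73.3%), were also marked. The members below 20% were Nebl (19.3%), the light chain genes Myl4 (17.2%), Myl3 (12.8%) and Myl7 (4.52%), and Tcap (0%). Low shares can go with long loci: Nebl had 74.7 kb covered of 388 kb, Myl4 7.75 kb of 45.1 kb and Myl3 3.57 kb of 27.9 kb. Each of these loci overlaps another annotated gene. Myl7, the atrial regulatory light chain gene of 2.15 kb, was covered over 0% in replicate 1 and 2.05% in replicate 2, Tcap over 0% and 16.2%, and Nebl over 18.0% and 12.4%.

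Cardiac transcription factor genes were divided. Of 23, 11 were marked, and the median share was 16.7% (percentile 94.7 of random lists). Gata6 (87.2% in the replicated list, 79.3% ± 2.82 in the replicates), Tbx20 (83.9%, 78.0% ± 5.97) and Hey2 (62.2%, 56.0% ± 7.73; SD, n = 2 each) had the largest shares, with Tbx5 at 57.5%, Srf at 56.2% and Myocd at 54.4%. Gata4, an early regulator of heart formation, had 37.5%. Nkx2-5, another such regulator, had 16.7% in the replicated list, 9.60% in replicate 1 and 17.3% in replicate 2. Hand1, Isl1 and Pitx2 had no peak base in either replicate or the replicated list. Some unmarked members had long loci with many covered bases, such as Foxp1 (52.8 kb of 597 kb), Tead1 (36.2 kb of 227 kb) and Mef2c (22.3 kb of 163 kb). By replicate 2's own list the percentile of this list passed the middle 95% of random lists, and by that of replicate 1 it did not.

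Genes of conduction and calcium handling were marked in 11 of 17 cases, with a median share of 29.6% (percentile 99.7). At a covered share of 40% the count was 5, and against random lists without length matching the percentile was 96.4, inside the middle 95%. Below Atp2a2 came Kcnh2, a repolarising potassium channel gene, with 66.4%, and Pln, the gene of the pump's inhibitor phospholamban, with 52.4%, the latter covered over 49.7% in replicate 1 and 24.3% in replicate 2. The pacemaker channel gene Hcn4 had 9.07% (3.78% and 4.91% in replicates 1 and 2). The atrial potassium channel gene Kcnj3 had 0% in the replicated list, but had peak bases in at least 1 replicate's own list.

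Lists for the other cell types of the heart had smaller medians than the cardiac muscle list. Of 16 endothelial genes 6 were marked, with a median of 14.9% (percentile 82.7). Eng (48.6%), Notch1 (43.1%) and Kdr (39.6%, with 29.5% and 21.9% in replicates 1 and 2) led. Sox17 and Erg had 0% in the replicated list, but at least 1 of them had peak bases in a replicate's own list. The count of marked endothelial genes was 10 at a covered share of 10%, 2 at 40%, and 2 with peaks held over at least 50% of their length in each replicate. Of 17 genes of fibroblasts, epicardium and matrix 10 were marked, 6 at a covered share of 40% and 3 with peaks so held, with a median of 29.4% (percentile 93.1). Fn1, the fibronectin gene, had 93.1% in the replicated list and 88.9% ± 4.43 (SD, n = 2) in the replicates, Sparc 67.1% and Vcan 60.4% (60.4% and 36.7% in replicates 1 and 2), while Tcf21, Aldh1a2 and Upk3b had 0%. Of 12 smooth muscle and pericyte genes 8 were marked, 5 at a covered share of 40%, with a median of 35.5% (percentile 93.9), led by Cnn1 (71.9%; 68.2% and 43.5% in replicates 1 and 2), Smtn (70.0%) and Acta2 (65.4%). Myh11, Rgs5 and Lmod1 had no peak base. None of these 3 medians passed the middle 95% of random lists.

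Few blood genes were marked. Random lists held a median of 4 marked genes for either list. The erythroid count of 1 lay at percentile 1.985, with ties counted in part, on the lower edge of the middle 95% of random counts (1 to 8). The myeloid count of 2 lay at 10.765, inside the middle 95%. Of 16 erythroid genes only Tfrc, the transferrin receptor gene used by many dividing cells, was marked (76.3%), and all 7 globin genes in the list had no peak base. Of 14 myeloid genes 2 were marked, 1 at a covered share of 40%. Cd68 was covered over 100%, but the peak over it, on chromosome 11 (69663508 to 69667104), also lay in the neighbouring translation factor gene Eif4a1. Cx3cr1 had 24.7%, and its annotated locus overlaps 5 other coding genes, among them the muscle gene Xirp1, where its longest overlapping peak lay. Csf1r had 9.38%, and Ptprc, Spi1 and Adgre1 had none.

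Genes of tissues other than heart carried almost no mark. No member was marked among 18 neuronal, 16 liver and 14 lung and foregut epithelium genes, and in each list 1 member held any replicated peak base: Elavl3 (0.962%), Hnf1a (1.41%) and Sftpb (3.64%). Of 14 genes of skeletal muscle and its progenitors 1 was marked, Ckm (26.6%), the muscle creatine kinase gene, which was over the threshold in replicate 2 (22.4%) and below it in replicate 1 (19.1%); none was marked at a covered share of 40% or with peaks held over 50% in each replicate. Myod1, Myf5 and Pax7 had none. Since the medians of these lists are 0, as are those of many random lists, their percentiles are not informative; the random lists held a median of 6 marked genes for neurons, 6 for liver, 4 for lung and foregut and 5 for skeletal muscle.

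Lists of cell cycle genes, housekeeping genes and enzymes of the mark had high medians. All 16 cell cycle genes were marked in both replicates and the replicated list, with a median of 76.4%, led by Top2a (94.6%), Mcm2 (91.1%) and Bub1b (89.3%). Of 20 housekeeping genes 19 were marked, with a median of 68.3%; the exception was Tuba1b (15.2%; 5.16% in replicate 2). Of 17 genes of enzymes and readers of the mark 13 were marked (median 58.9%), among them Setd2, which encodes the methyltransferase that lays it down, with 60.4% in the replicated list and 54.7% ± 4.01 (SD, n = 2) in the replicates, the demethylase gene Kdm4a with 91.1% and the reader gene Psip1 with 84.4%. Dnmt3b had the smallest share, 9.59%. Each of these 3 lists had a percentile of 100.

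**Figure D3:**
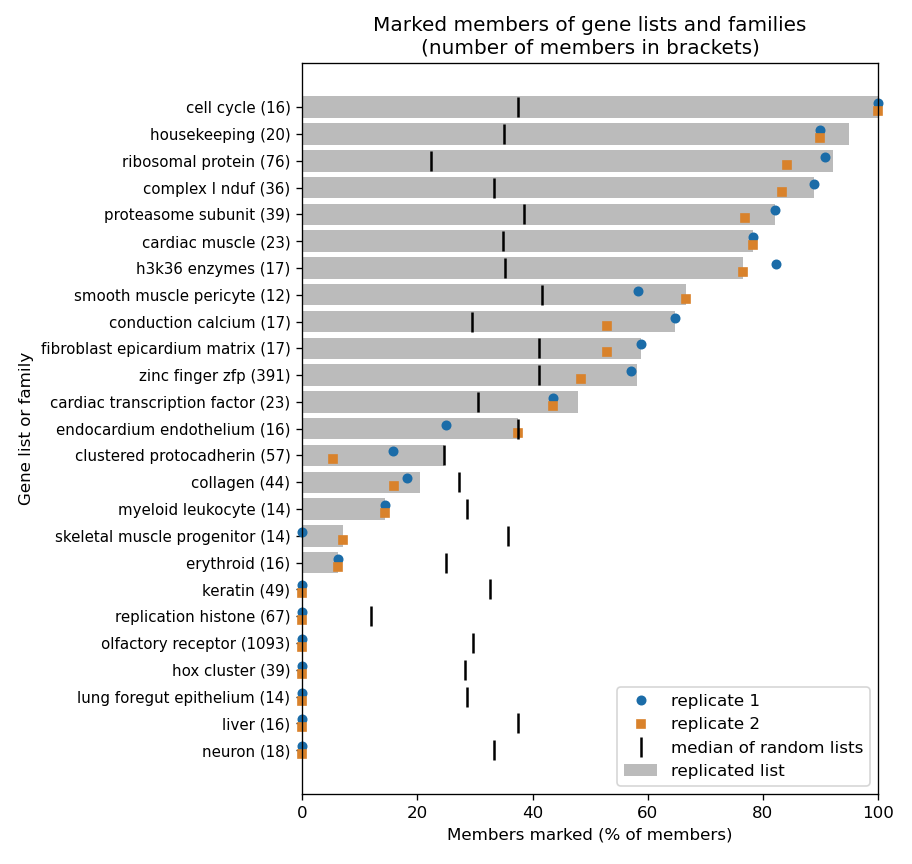
Share of members marked (x axis, % of members) in each gene list or family (y axis, number of members in brackets); bars give the replicated list, points each replicate's own list and ticks the median of 10000 random lists matched on gene length. Cell cycle (100%), housekeeping (95%) and ribosomal protein genes (92.1%) lead, cardiac muscle genes reach 78.3%, and 7 lists and families have no marked member.

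Families set by name ranged from nearly all members marked to none. Ribosomal protein genes were marked in 70 of 76 cases (median 61.6%), complex I subunit genes in 32 of 36 (61.0%) and proteasome subunit genes in 32 of 39 (63.4%), each at percentile 100, with Rps15a (88.6%), Ndufa10 (88.7%) and Psmc4 (89.0%) as the most covered members. Zinc finger genes with Zfp symbols were marked in 227 of 391 cases, 146 at a covered share of 40% (median 26.4%, percentile 100), led by Zfp869 (99.7%). Of 44 collagen genes 9 were marked. Col6a1 (50.4%; 41.8% and 31.7% in replicates 1 and 2) and Col1a1 (50.2%; 22.2% and 34.5%) led in the replicated list. Col4a1 lay above both in each replicate's own list (42.2% and 40.7%). The count was 4 at a covered share of 40%, and 4 with peaks held over at least 50% of their length in each replicate. No member was marked among 1093 olfactory receptor, 39 Hox, 67 replication histone and 49 keratin genes. At a covered share of 10%, 1 histone and 1 keratin gene were. These counts include genes shorter than 1 kb, such as Hist1h1a (0.741 kb) and Olfr1008 (0.942 kb). Clustered protocadherin genes were marked in 14 of 57 cases in the replicated list, but in 9 and 3 in the lists of replicates 1 and 2, and members such as Pcdhgc3 and Pcdhga8 share the same 3′ bases; the count was 3 with peaks held over 50% in each replicate and 0 at a covered share of 40%.

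The X chromosome had the smallest covered share of gene bodies of the chromosomes other than Y. Peaks of the replicated list covered 4.03% of its protein-coding gene body bases, against 10.1% to 18.5% on the 19 autosomes (median 13.4%), and 15.2% of its genes were marked against 29.5% to 45.8%. Replicate 1 covered 4.18% of X gene bodies, against 9.85% to 17.6% on the autosomes, and replicate 2 covered 2.51%, against 7.49% to 14.4%. The ratio of replicate 2 to replicate 1 was 0.602 on the X and 0.746 to 0.822 on the autosomes. Covered shares count called peaks, not the amount of the mark. Peaks of replicate 1 were weaker on the X, with a median −log10 p of 5.36 against 6.20 on the autosomes. Among housekeeping genes on the X, Pgk1 had 76.9% in the replicated list (66.0% and 62.4% in replicates 1 and 2), and Hprt 32.5% (28.8% and 19.8%, the latter below the threshold). Chromosome 11 had the largest covered share, 16.0% ± 2.26 (SD, n = 2), and chromosome Y had 0.102% with no marked gene among 163.

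**Figure D4:**
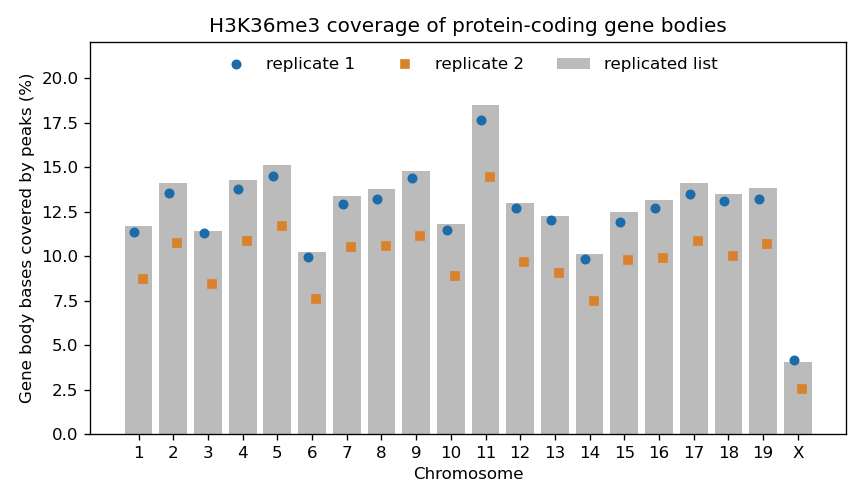
Share of protein-coding gene body bases covered by H3K36me3 peaks (y axis, %) on each chromosome (x axis); bars give the replicated list and points each replicate. The X, at 4.03%, lies below all 19 autosomes, which range from 10.1% to 18.5%.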

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

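All alternatives were fixed before the data were examined, except the settings for genes marked in 1 replicate only and the peaks with at least 50% of their length in each replicate, which were chosen after. Where no cause is named, the cause was not tested. With a q-value of at most 0.01, the Jaccard index of the replicates was 0.584, the correlation across genes 0.974, and the shares of peaks found in the other list 48.6% for replicate 1 and 80.3% for replicate 2. An overlap of 1 bp gave 66.5% and 85.1%, and a reciprocal overlap of 50% gave 33.5% and 32.8%.

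With the pooled list, the gene body ratio was 2.42 and the ratio of bins 11 to 20 over bins 1 to 10 was 1.73. With peaks held over 50% in each replicate (68568 of 111540), the gene body ratio was 2.44, the bin ratio 1.93, the exon to intron ratio 2.13 and the covered share of X gene bodies 2.38%. Counting all annotated genes gave a gene body ratio of 2.08. The bin ratio was 2.06 in genes of at least 50 kb and 1.86 in all genes of at least 10 kb, marked or not. The exon to intron ratio without first exons and introns was 1.71. Over all bases of the chromosome, 1.196% of the X was covered. Among genes that overlap no other gene, 3298 were marked, from fewer genes tested.

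Using 1 replicate's list alone, the ranges were 2.43 for the gene body ratio in both, 1.81 to 1.88 for the bin ratio, 1.96 to 2.24 for the exon to intron ratio and 2.51% to 4.18% for the X. The number of lists and families above the middle 95% of random lists, 9, stayed between 8 and 10: conduction and calcium handling fell inside it without length matching, and cardiac transcription factors passed it by replicate 2's list and against genes that overlap no other gene. In the 18 lists and families with a marked member, 108 of 126 counts of marked members lay within 1.5 times the main count; the other 7 have a main count of 0, where this comparison says little. With peaks held over 50% in each replicate, 2 endothelial, 3 fibroblast, epicardium and matrix, and 3 clustered protocadherin genes were marked in place of 6, 10 and 14. At a covered share of 10%, 8816 genes were marked, and at 40%, 5285. Depth is unknown, so a gene without peaks may carry the mark below the peak threshold.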

Other observations

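The noncoding genes and the tests of short genes reported here were chosen after the data were examined, as were the comparison of the X with GC matched together with −log10 p, the differences within groups of genes by coverage and by length and the use of 5 lists of broadly used genes as controls; the other tests were set before their results were seen. Outside protein-coding genes, 50 of 4963 lincRNA genes of at least 1 kb were marked. Mir17hg, the host gene of the miR-17 cluster, on chromosome 14 (115042879 to 115046727), was covered over 98.0% in the replicated list, and Malat1, an abundant nuclear RNA gene on chromosome 19 (5795690 to 5802672), over 74.3%. Neat1, its neighbour, had 0% (1.31% in replicate 1). The imprinted gene Meg3 on chromosome 12 had 46.7%, with 38.5% in replicate 1 and 26.3% in replicate 2. H19, another imprinted gene with high expression in embryonic tissues, had 10.9%, with 0% in replicate 1 and 23.4% in replicate 2. On the X, Ftx had 26.3%, with 27.2% in replicate 1 and 15.4% in replicate 2, and Firre 20.8%, with 19.6% and 8.72%.

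X-linked gene bodies lost more coverage from replicate 1 to replicate 2 (ratio 0.602) than those of any autosome (0.746 to 0.822). If −log10 p alone set how often a peak is found in replicate 2, X and autosomal peaks of the same −log10 p would be found equally often. Of 4116 X peaks of replicate 1, 33.0% were found (exact 95% binomial interval 31.6% to 34.5%) against 43.1% of matched autosomal peaks, a difference of -10.06 percentage points. That interval treats peaks as independent, though many lie in the same genes, so it is too narrow. With 1 pair of libraries, it does not measure spread between replicates. The matching left out the lower coverage of the X, so weak peaks are not excluded as the cause. The X had a lower GC content (median 41.4% over genes with peaks, against 45.9% on autosomes). As the only cause, it would need autosomal genes matched on GC to lose as much. Their ratio was 0.7462, against 0.787 for autosomal genes without matching, so GC alone went only part of the way. This match left out coverage as well. Among the least covered marked genes of all chromosomes, those with the lowest GC had a ratio of 0.682. GC acting on weakly covered genes is therefore not excluded. Matching −log10 p and GC together gave 41.6% for the autosomes as a whole and 39.5% to 44.3% for the autosomes one by one, all above the X. A different mix of male and female embryos in the pools, or a control with another X dosage, also stays open. Coverage of the Y-linked genes Kdm5d (6.10% and 0.944%) and Ddx3y (5.77% and 0.785%) was also lower in replicate 2, but is too near 0 to decide.

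Replicate 1 covered 135 Mb and replicate 2 106 Mb with similar numbers of peaks. Among 22705 overlapping peaks with signals within 10% of each other, −log10 p was larger in replicate 1 by a median factor of 1.201 (quartiles 1.10 and 1.31), at the edge of the bound of 1.2 set for a deeper replicate 1, so more reads in replicate 1 may be part of the cause. GC content also may contribute: the ratio of covered bases, replicate 2 over replicate 1, was 0.746 in the fifth of marked genes with the lowest GC and 0.921 in that with the highest, a difference of 0.1747, and the difference was 0.111 to 0.217 within 3 equal groups of genes by coverage, and, since median gene length fell from 38.2 kb at the lowest GC to 8.52 kb at the highest, 0.143 to 0.155 within 3 groups by length and 0.0791 to 0.270 within the 9 groups by both. A different share of cell types was tested with 4 lists: cardiac muscle genes had a mean share of 52.4% in replicate 1 and 53.3% in replicate 2, a difference at percentile 0 of random lists matched on coverage, and the endothelial list lay at 0.06, while fibroblast, epicardium and matrix genes (3.21) and smooth muscle genes (8.09) lay inside the middle 95%; with GC matched as well, 3 of the 4 lay outside. Of 5 control lists, ribosomal protein (percentile 0) and housekeeping genes (1.98) also lay outside, and cell cycle, complex I and proteasome genes (13.85 to 39.56) inside, so the test is not specific to cell types and their shares stay open.

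Of 3 cardiac muscle list genes of 1 to 5 kb, Myl7 (4.52%) and Tcap (0%, but 16.2% in replicate 2) had little coverage in the replicated list. The mark is sparse near the TSS, which could leave genes of 1 to 5 kb bare, but 58 ribosomal protein genes of that length had a median covered share of 61.31%, and 55 of them were marked. Genes of this length can therefore carry the mark, and Tnnc1, at 3.42 kb, had 51.4%. Ribosomal protein genes were a highly marked family and were not matched on length to Tcap (1.14 kb) or Myl7 (2.15 kb). A gap near the TSS is thus not excluded for Tcap and Myl7. No biological explanation was tested, since the series holds no expression data and no separate chambers.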
